A study of Mus musculus with 8 samples.

How the data were processed

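Single-nucleus ATAC-seq, in which a transposase cuts and tags open chromatin, was run on sorted bone marrow cells of C57BL6/J mice in 8 libraries (2 control, 3 stroke, 3 stroke-treated). The authors deposited 1 joined matrix of counts, whole numbers of transposase cut sites per peak and nucleus, with no normalisation, made by alignment and peak calling with Cell Ranger ATAC 2.1.0 on mm10, per the labels and the file headers. It held 266867 peaks, with a median width of 867 bp, and 55706 nuclei, and 91% of its nonzero entries were even, because both ends of a fragment were usually counted. The largest entry was 714. Whether the libraries were subsampled to equal depth when they were joined is not given in the sources used here. Nuclei were assigned to libraries by reading the numeric suffix of the barcode as the sample number of the labels, which the files do not state outright.

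For clusters and classes, nuclei with at least 1000 counts in peaks were kept (52557, with 5.65% left out). Sums over all nuclei, and signal concentration over them, held all 55706 nuclei. The 60000 peaks open in most nuclei were weighted by term frequency and inverse document frequency and reduced to 30 components (latent semantic indexing; scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15, seed 1). The first component was dropped, since it correlated with depth at 0.93. Leiden clustering on 20 nearest neighbours (leidenalg 0.10.2, igraph 0.11.9) gave 19 clusters at resolution 0.8, and 17 and 26 at 0.4 and 1.2. Clusters were named from 16 marker lists of cell types, with the suffix -like because chromatin alone names them. The names were given by hand once the clusters were known, and clusters without a clear list stayed unnamed. Cluster 0 was joined to the monocyte-like class although its stromal list had the higher median log2 fold (0.49, against 0.34 for the monocyte list), so its name is uncertain. No doublet caller was run; an alternative left out the 5% of nuclei with the highest counts in each library.

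Gene accessibility was the sum of the counts of all peaks that overlap a gene's span (GRCm38.p6) or 2 kb on both sides of it. The plan named 2 kb upstream, but the gene table used here gives no strand and no exons, so the position of a peak within a gene is not given. Of 21883 protein-coding genes, 18542 had a peak, with a median of 4 peaks, and 47% of peaks lay in a gene span. Overlapping genes share peaks. Counts were summed per library over all nuclei, over monocyte-like nuclei and over HSPC-like nuclei, since the library and not the nucleus is the replicate. A library with under 50 nuclei of a class was left out of that class, which removed Stroke 1 from the HSPC-like fits.

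Changes were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) in 1 fit of all 8 libraries. Scaling was by TMM factors, features passed filterByExpr, and p-values were adjusted after Benjamini-Hochberg with a threshold of 0.05. The tests are two-sided. Fold changes are log2 values from the edgeR fit with its default prior count. Their standard errors (SE) were derived from the fold change and its F statistic. Accessibility per library is given as CPM, counts scaled to the same library size. Log2 CPM values, used for gene sets and for values relative to T-like nuclei, had a prior count of 2. TMM factors ran from 0.970 to 1.03 for genes over all nuclei and from 0.617 to 1.87 for peaks of monocyte-like nuclei. The biological coefficient of variation was 16.2% for genes over all nuclei, 23.1% in monocyte-like and 9.47% in HSPC-like nuclei, and 24.4% and 33.7% for peaks. Class shares were tested with the same edgeR test on nuclei per class and with the exact permutation test. The fits were tested on simulated data with 100 changed features per fold, where 0 to 13 features were called in error. All changed features lay above the median accessibility, and only a sample of the peaks was simulated. No difference shared by a whole library or set of libraries was simulated.

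For gene sets, 27 lists were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, adjusted over the lists of 1 comparison and nuclei set, and again with the correlation estimated from the data. The lists were the 16 marker lists and 11 lists of pathways: IL-1 and NF-κB signalling, interferon response, migration, matrix remodelling, myeloid transcription factors, AP-1 family, glycolysis with mTOR and cholesterol synthesis, antigen presentation, chromatin enzymes, pattern recognition receptors and growth factor receptors. Of 422 list entries, 416 matched a gene. Some genes are on several lists. The reversal of stroke changes was measured as the correlation across genes of the log2 fold changes of both comparisons, beside 20 simulated draws of unchanged groups.

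Comparisons, tests, lists, thresholds and the rule for naming genes were set before the data were examined. By that rule, each main comparison and nuclei set names the 5 genes up and the 5 down with the largest log2 fold change among those that passed and lay above the median accessibility, filled where too few passed with the smallest unadjusted p. It adds the 2 members of each pathway list with the smallest unadjusted p, and always Il1b, Il1r1, Ccr2, Ly6c2, Mmp9, Nlrp3, Spi1, Cebpb and Irf8. Up to 3 peaks per direction were to be named among those that passed. Predicted genes and genes summed from the same peaks as another named gene were avoided, and stroke-treated against control was to be given as a summary.

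The alternatives were DESeq2 1.42.0, RLE factors, no scaling factor, no filter beyond 1 count, binarised counts, only the groups compared, a threshold of 0.1, the replicate number as a block, each library left out in turn, other clustering resolutions, at least 3000 counts per nucleus for the class shares, and the estimated correlation. Further ones were chosen after seeing the data: signal concentration (the percent of a library's counts in the 1000 strongest peaks over all nuclei) as a covariate, the set of libraries by sample number as a block, only the 4 libraries with the most nuclei, gene spans without flanks, monocyte-like nuclei without cluster 0, and values relative to T-like nuclei of the same library. Signal concentration differed between control and stroke-treated libraries, so as a covariate it also took up group differences, whatever their cause. Values relative to T-like nuclei were tested with limma on differences of log2 CPM. Promoter accessibility and motif enrichment were planned and were not run, since strand and genome sequence were not used here.

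Depth ran from 2221962 counts in Stroke 1, where values are the least precise, to 113887725 counts in Stroke-treated 2. The 95% intervals of shares in single libraries are Wilson intervals. They cover counting error only, as cut sites come in pairs and are not independent. Figures were drawn with matplotlib 3.10.9.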

Results

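Chromatin accessibility was measured in single nuclei of mouse bone marrow, long after an experimental stroke. The 8 libraries formed 3 groups: control mice (n = 2), stroke mice (n = 3) and stroke mice given a neutralizing antibody against IL-1β, called stroke-treated (n = 3). Before lysis, live cells were sorted without T cells, B cells, erythroid cells and mature neutrophils, which leaves mainly progenitors and other myeloid cells. The control libraries held 4413 and 11693 nuclei with 41569394 and 111124692 counts in peaks. The stroke libraries held 304, 4127 and 10114 nuclei with 2221962, 30391298 and 89986701 counts, and the stroke-treated libraries held 1773, 13079 and 10203 nuclei with 10438430, 113887725 and 71967846. The median count per nucleus ran from 4243 in Stroke 1 to 9456 in Control 2. The labels do not state whether the libraries of a group came from different animals, so the p-values measure the spread between these libraries, which may be technical.

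By marker lists, the nuclei ranged from stem and progenitor cells to monocytes. The class called monocyte-like was the most frequent, with 38.9% ± 0.902 of nuclei in control (SD, n = 2), 36.8% ± 10.9 in stroke (SD, n = 3) and 43.6% ± 8.41 in stroke-treated libraries (SD, n = 3). It holds clusters 0, 1 and 12, with 11282, 8351 and 1366 nuclei, and cluster 0 is named with little certainty: against the other nuclei its highest marker lists were the stromal, eosinophil and macrophage ones, and its leading genes, such as Dkk2 and Igf1, are not monocyte markers. Granulocyte-monocyte progenitor (GMP)-like nuclei made up 10.6% ± 2.34, 10.1% ± 1.23 and 11.9% ± 1.69. Their name is uncertain: 6 of 10 GMP genes lay between Elane at a log2 fold of 0.68 and Ctsg at 0.95 against the other nuclei, but neutrophil and monocyte markers were higher too, and the leading genes, such as Trem2, Pilra and Cd40, hold no GMP gene. Haematopoietic stem and progenitor (HSPC)-like nuclei made up 4.06% ± 0.381, 2.73% ± 1.33 and 3.72% ± 0.448. Their name is uncertain too: 5 of 14 HSPC genes were over 2-fold against the other nuclei. The median log2 fold was 0.88 for that list, 0.70 for the megakaryocyte and 0.58 for the B lineage list. The leading genes, such as Rnf224 and Ackr3, hold no gene of the HSPC list. Plasmacytoid dendritic (pDC)-like nuclei made up 6.48% ± 0.535, 4.46% ± 1.79 and 4.09% ± 1.56, and conventional dendritic (cDC)-like nuclei 3.41% ± 0.0981, 2.27% ± 1.69 and 2.60% ± 0.894. T-like nuclei, which the sort should have removed, made up 13.9% ± 2.87, 10.9% ± 0.722 and 12.7% ± 2.65, and NK-like nuclei 6.94% ± 1.04, 5.96% ± 1.23 and 6.92% ± 0.951. Clusters left unnamed held 8.00% ± 1.07, 19.8% ± 19.7 and 7.27% ± 2.07. The largest of them, cluster 9, held 2003 nuclei of low depth, with a median of 1774 counts. Its highest marker list was the erythroid one, with 5 of 12 genes over 2-fold, but its leading genes, such as Ugt1a1 and Otog, hold no erythroid gene. Only 2.91% of its counts lay in the 1000 strongest peaks, the lowest value of all clusters. The next lowest was 6.83%, in cluster 6. Nuclei of cluster 9 remain in the sums over all nuclei. In Stroke 1 the unnamed clusters held 42.2% of 251 nuclei (95% Wilson interval 36.3 to 48.4%), and cluster 9 alone held 102.

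No class share changed past the threshold in any comparison with all libraries. Without Stroke 2, the unnamed nuclei passed in stroke-treated against stroke (log2 ratio -1.83, edgeR adjusted p = 0.0175), a comparison in which Stroke 1 with its 251 nuclei was 1 of 2 stroke libraries. The smallest adjusted p (edgeR, Benjamini-Hochberg over 11 classes) was 0.848 for stroke against control, 0.637 for stroke-treated against stroke and 0.993 for stroke-treated against control. The smallest p that the two-sided exact permutation test can give for these group sizes is 0.1, and T-like nuclei reached it in stroke against control.

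**Figure D1:**
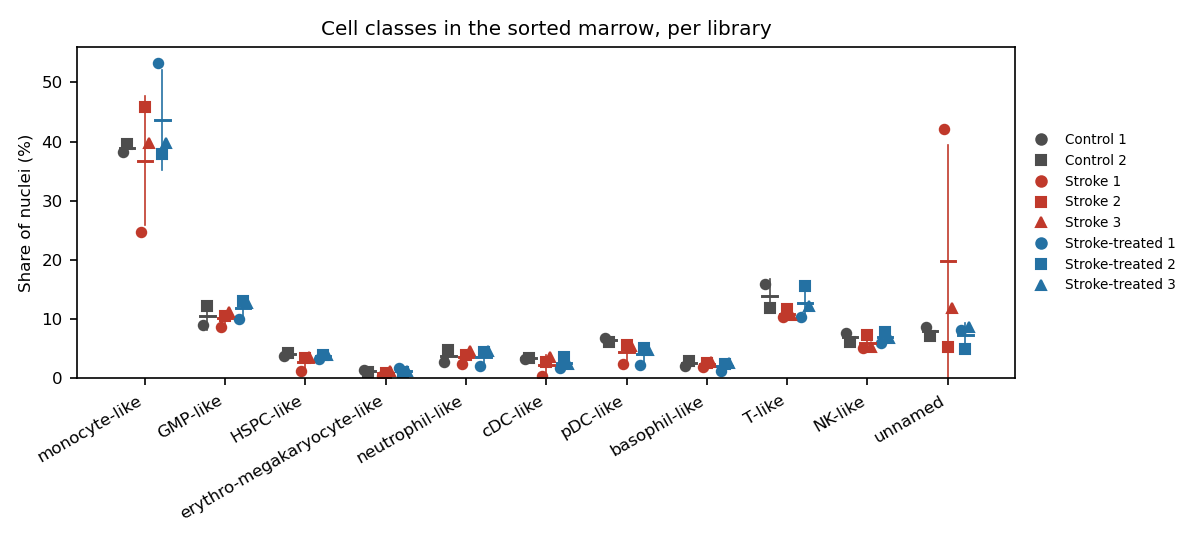
Share of nuclei (y axis, percent) in each cell class (x axis) for the 8 libraries; points are libraries and bars are group means with the SD. Control libraries sat at 38.9% ± 0.902 monocyte-like nuclei, within the range of the other groups.

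The libraries differed in how strongly their counts gathered in open peaks. The 1000 strongest peaks took 11.3% of the counts in both control libraries. They took 8.74, 8.53 and 11.2% in Stroke 1, 2 and 3, and 7.06, 9.96 and 8.36% in Stroke-treated 1, 2 and 3. The widest 95% Wilson interval of these, that of Stroke 1, ran from 8.71 to 8.78%. Over nuclei of 4000 to 8000 counts only, the control libraries had 12.2 and 12.8%, the stroke libraries 8.34, 8.81 and 12.1%, and the stroke-treated libraries 7.16, 10.8 and 8.75%. Among T-like nuclei the share was 13.5 and 13.3% in control and 10.985, 12.8 and 11.4% in stroke-treated libraries. It was 13.1, 11.5 and 13.3% in Stroke 1, 2 and 3, with 26 T-like nuclei in Stroke 1. Monocyte-like nuclei consisted of 3 clusters whose weights differed in the same way. Cluster 0, in which 10 of 15 monocyte genes were more accessible than in other classes (median log2 fold 0.34, and 0.49 for stromal markers), held 33.1 and 14.6% of monocyte-like nuclei in Control 1 and 2, and 61.3, 86.1 and 28.2% in Stroke 1, 2 and 3. It held 93.9, 70.4 and 87.6% in Stroke-treated 1, 2 and 3. Cluster 1, in which 14 of 15 monocyte genes were more accessible, held 56.9 and 75.2%, then 35.5, 9.22 and 66.1%, then 1.93, 25.3 and 6.46%. The 95% Wilson intervals were widest in Stroke 1, with 48.8 to 72.4% for cluster 0 and 24.7 to 47.9% for cluster 1, and next in Control 1, with 30.8 to 35.5% and 54.5 to 59.4%.

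**Figure D2:**
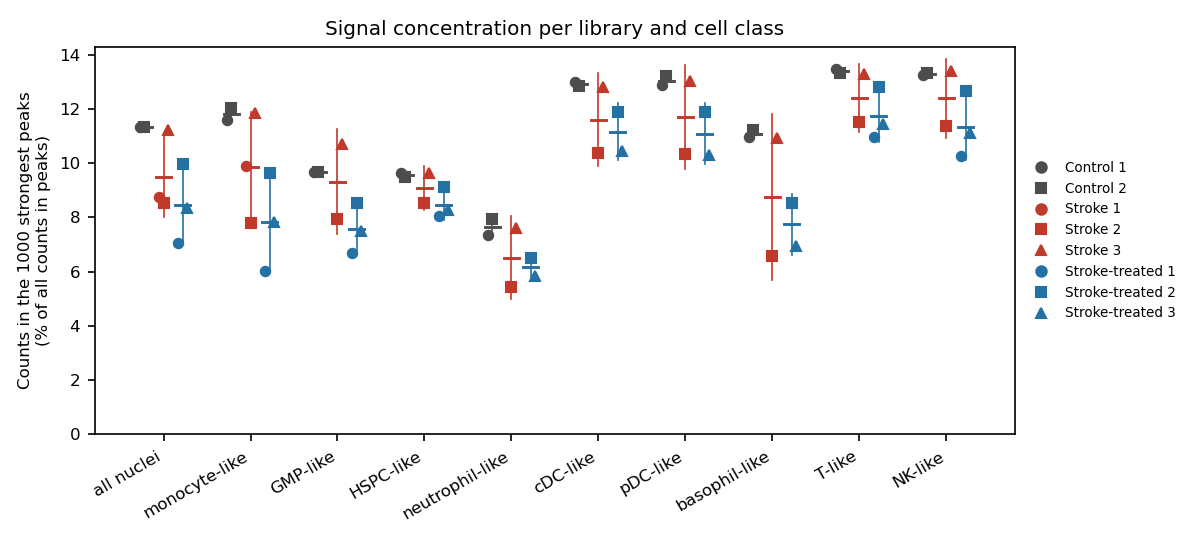
Percent of a library's counts in peaks that fell in the 1000 strongest peaks (y axis), for all nuclei and for single cell classes (x axis); points are libraries and bars are group means with the SD. Both control libraries lay at 11.3% over all nuclei, and the stroke-treated libraries between 7.06 and 9.96%.

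The first comparison, stroke against control, asks whether a past brain injury left marks on the chromatin of marrow cells. Over all nuclei, genes of the AP-1 family, transcription factors that open chromatin after inflammatory stimuli, were less accessible in stroke libraries, with 16 of 17 members lower and a median log2 fold change of -0.19. Atf4, a factor of the stress response, had 95.1 ± 21.6 CPM (counts scaled by library size; SD, n = 3) in stroke and 123 ± 4.85 (SD, n = 2) in control libraries. Jund, an AP-1 subunit, had 128 ± 26.4 in stroke and 160 ± 0.0668 in control libraries. The list passed in camera (adjusted p = 0.0373), but not with an estimated correlation (adjusted p = 0.828). Leaving out 1 library gave 0 passing lists without Stroke 2, 8 without Control 1, 3 without Stroke 1, 3 without Control 2 and 2 without Stroke 3. With gene spans without flanks 0 lists passed.

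The other lists over all nuclei missed the threshold. Genes of glycolysis, mTOR and cholesterol synthesis, the metabolism tied to trained immunity, were lower in 20 of 24 cases (camera adjusted p = 0.0679). Among them Mvk, an enzyme of the mevalonate pathway, had 61.3 ± 12.4 CPM in stroke and 76.1 ± 0.580 in control libraries. Antigen presentation genes were lower in 13 of 16 cases (0.0923), with the class II gene H2-Ab1 at a log2 fold change of -0.26 (SE 0.11) and its invariant chain Cd74 at -0.24 (SE 0.13). Chromatin enzymes were lower in 19 of 23 cases (0.119) and myeloid transcription factors in 17 of 21 (0.13). Examples were the histone demethylase Kdm5a at -0.26 (SE 0.13) and Egr2 at -0.22 (SE 0.13), while Mafb, which drives macrophage fate, was at 0.24 (SE 0.14). Pattern recognition receptors were higher in 18 of 23 cases (0.131), such as the flagellin receptor Tlr5 at 0.34 (SE 0.14) and Fpr1 at 0.80 (SE 0.36).

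Among the 30 genes of IL-1 and NF-κB signalling, 20 were lower and 10 higher in stroke libraries (camera adjusted p = 0.287). Ptgs2, which makes the inducible cyclooxygenase (chromosome 1, 150100031 to 150108234, mm10), had 27.2 ± 7.61 CPM in stroke and 16.9 ± 0.818 in control libraries. Tnf had 42.1 ± 7.69 and 55.7 ± 2.06 CPM. Il1b itself (chromosome 2, 129364569 to 129371164) had 28.7 ± 8.22 and 32.6 ± 4.59 CPM, a log2 fold change of -0.11 (SE 0.20). Its receptor Il1r1 was at -0.09 (SE 0.13), the inflammasome sensor Nlrp3 at -0.03 (SE 0.12), and the monocyte chemokine receptor Ccr2 at 0.11 (SE 0.21). The lineage factors Spi1, Cebpb and Irf8 were at -0.11, -0.15 and -0.17, Ly6c2 at -0.11 and the protease gene Mmp9 at 0.00. Interferon response genes were lower in 13 of 20 cases (0.385), with Gbp5 at 0.54 (SE 0.26) and Usp18 at -0.19 (SE 0.11). Genes of migration (10 of 18 higher), matrix remodelling (12 of 22 higher) and growth factor receptors (9 of 14 lower) each had an adjusted p of 0.826. The camera direction was down for migration and matrix genes, although their medians were 0.01 and 0.02. Among these, the integrin gene Itgb1 was at 0.30 (SE 0.12) and the metalloproteinase gene Mmp19 at 0.73 (SE 0.27).

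Marker lists of cell types did not pass in this comparison. The erythroid list (9 of 12 higher) and the stromal list (8 of 10 higher) had a camera adjusted p of 0.13. The eosinophil list (6 of 8 higher) had 0.162 and the megakaryocyte list (6 of 9 higher) 0.187. The HSPC, neutrophil, macrophage, B lineage and basophil lists were higher and the monocyte list was lower, each with 0.385. The GMP list had 0.583, the conventional dendritic list 0.782, the plasmacytoid dendritic and plasma cell lists 0.826, and the T cell and NK lists 0.94.

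No gene over all nuclei passed in edgeR (0 of 18542, Benjamini-Hochberg) in stroke against control, and DESeq2 gave 0. At an unadjusted p under 0.05 there were 794 genes (4.28%), 720 higher and 74 lower in stroke libraries. In simulated data 4.74% of unchanged genes had such a p, so the total is not above that share. The simulation drew genes independently, with no difference shared by a whole library, so it gives no reference for the one-sided split. Nearest to the threshold, with an adjusted p of 0.607, were Sdr16c6 at 1.16 (SE 0.30), Rorb at 1.19 (SE 0.34), Krt75, Lipn and Liph on the higher side. On the lower side were Rdm1 at -0.53 (SE 0.13), Klhdc9, Pdcd5, Polr1b, a subunit of RNA polymerase I, and the ribosomal protein gene Rps27 at -0.43 (SE 0.15). No member of any list passed when adjusted over the list alone (count 0). In simulated data with this spread, 15% of 1.5-fold changes and 100% of 3-fold changes were recovered. These changes were all in genes above the median accessibility, so less accessible genes are not covered. Of 266857 peaks, 0 passed in edgeR and 0 in DESeq2, with 15652 (5.865%) at an unadjusted p under 0.05.

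In monocyte-like nuclei, AP-1 genes were again lower in stroke libraries, with 16 of 17 members and a median of -0.20. Batf2 had 4.19 ± 0.458 CPM in stroke (SD, n = 3) and 9.58 ± 2.11 in control libraries (SD, n = 2), and Batf had 61.0 ± 11.7 and 86.6 ± 5.86. The list passed in camera (adjusted p = 0.0449), but not with an estimated correlation (adjusted p = 0.847). No other list passed. The call ended (0 lists) with signal concentration as a covariate, with the set of libraries as a block and without cluster 0, which held 14.6 to 33.1% of these nuclei in control and 28.2 to 86.1% in stroke libraries. Without Stroke 2 or Control 2 the count was 0 as well, without Stroke 1 it was 5, and without Stroke 3 or Stroke-treated 1 it was 2. Il1rap, the shared chain of IL-1 family receptors, had 145 ± 19.5 CPM in stroke and 101 ± 8.45 in control libraries, and the endotoxin receptor gene Tlr4 had 110 ± 17.2 and 80.4 ± 9.90. Further values higher in stroke were Ptgs2 at 0.92 (SE 0.34), the histone deacetylase Hdac2 at 0.46 (SE 0.19), the egress receptor S1pr1 at 0.79 (SE 0.33) and the TGF-β receptor Tgfbr2 at 0.44 (SE 0.20). Prkar1a, a regulatory subunit of protein kinase A, was at 0.70 (SE 0.18), Fam20a at 0.78 (SE 0.21) and Dmd at 1.92 (SE 0.53). On the lower side were Rps15 at -0.76 (SE 0.23), the splicing factor Sf3b4 at -0.76 (SE 0.27), the sterol regulator Srebf2 at -0.51 (SE 0.25) and Irf4 at -0.43 (SE 0.27). Il1b was at -0.30 (SE 0.27), Nlrp3 at -0.22 (SE 0.18), Ccr2 at -0.06 (SE 0.34) and Cebpb at -0.27 (SE 0.32). All of these single genes missed the threshold (edgeR adjusted p of 0.713 or more). Of 18507 genes 0 passed, DESeq2 gave 0, and 779 (4.21%) had an unadjusted p under 0.05, 729 of them higher and 50 lower in stroke libraries. Of 257105 peaks, 0 passed in edgeR and 0 in DESeq2, with 10956 (4.26%) at an unadjusted p under 0.05. Without Stroke 3, 1464 peaks passed, 1450 of them lower in stroke. Simulated 3-fold changes, all above the median accessibility, were recovered in 89% of genes and 1% of peaks.

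In HSPC-like nuclei no list passed, and each had a camera adjusted p of 0.95. Genes of IL-1 and NF-κB signalling were higher in 18 and lower in 12 of 30 cases. Outside that list, Tnfrsf1a, the main TNF receptor gene, had 55.9 ± 1.85 CPM in stroke (SD, n = 2) and 40.0 ± 3.38 in control libraries (SD, n = 2). Tnfrsf1b, which is not on it either, had 178 ± 11.3 and 150 ± 9.83 CPM. Il1rap was at 0.31 (SE 0.14), the sheddase gene Adam8 at 0.44 (SE 0.20) and Pttg1, which guards chromosome separation, at 1.00 (SE 0.26). Pcdhga8 was at 0.57 (SE 0.14), beside Pcdhgb4 and Pcdhga3, whose spans overlap and share peaks. Lower values were those of the inflammasome adaptor Pycard at -0.58 (SE 0.25), the cholesterol synthesis gene Hmgcs1 at -0.35 (SE 0.15), the zinc transporter Slc39a13 at -0.50 (SE 0.14) and the splicing helicase Snrnp200 at -0.77 (SE 0.22). Il1r1, with 114 ± 10.3 and 118 ± 3.61 CPM, was at -0.06 (SE 0.13), and Spi1 at -0.03 (SE 0.14). None of them passed: 0 of 17507 genes did in edgeR (smallest adjusted p 0.54), DESeq2 gave 0, and 492 (2.81%) had an unadjusted p under 0.05. Stroke 1, with 3 HSPC-like nuclei, was left out. Without Stroke 3, which leaves 1 stroke library, 25 genes passed.

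**Figure D3:**
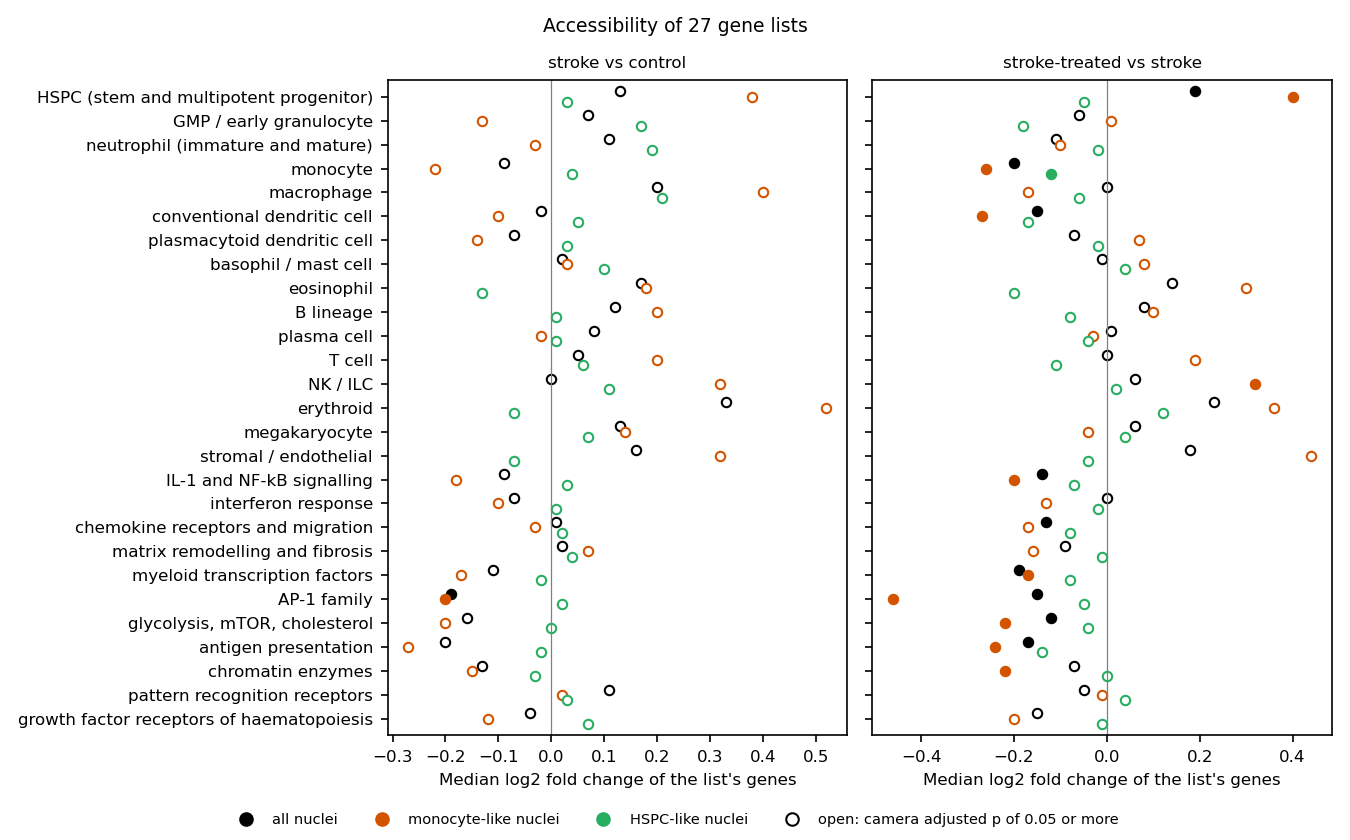
Median log2 fold change (x axis) of the genes of each of 27 lists (y axis), by comparison (panels) and nuclei set (colours); filled points passed in camera with the preset correlation, and no point would be filled with an estimated one. AP-1 genes lay at -0.19 over all nuclei and -0.20 in monocyte-like nuclei in stroke against control.

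The second comparison, stroke-treated against stroke, asks whether neutralizing IL-1β altered this chromatin state. Over all nuclei, monocyte genes were less accessible in stroke-treated libraries, with 14 of 15 members lower and a median of -0.20 (camera adjusted p = 0.00014; adjusted p = 0.686 with an estimated correlation). None of the 9 calls in this paragraph held with an estimated correlation, where the adjusted p was 0.798 for the metabolic list and 0.686 for each of the others. Lists of the AP-1 family (13 of 17 lower, adjusted p = 0.00931), myeloid transcription factors (16 of 21, 0.0117), antigen presentation (13 of 16, 0.0117), IL-1 and NF-κB signalling (22 of 30, 0.0147) and glycolysis, mTOR and cholesterol synthesis (21 of 24, 0.0147) passed. So did conventional dendritic markers (9 of 12 lower, 0.0259) and migration genes (13 of 18 lower, 0.0323). The HSPC markers were the 1 list that was higher (12 of 14 members, 0.0147). Signal concentration was 7.06 to 9.96% in stroke-treated and 8.53 to 11.2% in stroke libraries, and with it as a covariate 1 list passed.

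Nlrp3 (chromosome 11, 59541569 to 59566955) had 36.6 ± 1.29 CPM in stroke-treated (SD, n = 3) and 45.7 ± 2.82 in stroke libraries (SD, n = 3). The chemokine gene Ccl3 had 18.5 ± 0.926 and 23.2 ± 2.28 CPM. Trem1, a receptor that amplifies inflammation (chromosome 17, 48232713 to 48246927), had 43.0 ± 1.05 and 56.4 ± 4.53 CPM. The AP-1 genes Fosl2 and Junb were at -0.40 (SE 0.17) and -0.35 (SE 0.16), the immediate early factor Nr4a1 at -0.33 (SE 0.12), and Cebpb at -0.42 (SE 0.20). Rptor, the mTOR complex subunit, was at -0.30 (SE 0.12), the marrow retention receptor Cxcr4 at -0.28 (SE 0.11) and the class II gene H2-Eb1 at -0.31 (SE 0.16). The granule proteoglycan gene Srgn was at -0.31 (SE 0.10), the myeloid antigen Cd33 at -0.30 (SE 0.10) and the acetyltransferase Ep300 at -0.42 (SE 0.21). The ceramide synthase gene Cers4 was higher, at 0.40 (SE 0.11), as were Ihh, Rax, Sox13 and Olfr640. Il1b was at -0.18 (SE 0.18), Il1r1 at 0.05 (SE 0.11), Ccr2 at -0.28 (SE 0.19), Ly6c2 at -0.23 (SE 0.19) and Mmp9 at -0.27 (SE 0.16). None of these genes passed the threshold (edgeR adjusted p of 0.787 or more).

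Lists that missed it were growth factor receptors (0.071), chromatin enzymes (0.0719), neutrophil (0.0746) and erythroid markers (0.124). Plasmacytoid dendritic markers (0.226), stromal markers (0.25), pattern recognition receptors (0.286) and matrix remodelling (0.362) missed it as well. The remaining 10 lists, interferon response among them, had adjusted p from 0.709 to 0.807. Of 18542 genes, 0 passed in edgeR and 0 in DESeq2, with 235 (1.27%) at an unadjusted p under 0.05. Of 266857 peaks, 0 passed in both tools, with 5036 (1.89%) at an unadjusted p under 0.05. Both shares lay below the 4.74% of unchanged genes and of unchanged peaks simulated for stroke against control. No list member passed when adjusted over the list alone (count 0). With only the 4 libraries with the most nuclei, 336 genes passed, 320 of them higher; this fit holds 1 stroke library, assumed to vary like the 2 stroke-treated ones. Without Stroke 3, 0 lists passed, and without Stroke-treated 1, 4 did.

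In monocyte-like nuclei 8 lists were lower and 2 higher in camera, and with an estimated correlation each of these 10 lists had an adjusted p of 0.554. AP-1 genes were lower in 15 of 17 cases with a median of -0.46 (camera adjusted p = 0.00936), and IL-1 and NF-κB genes in 23 of 30 (0.0179). Metabolic genes were lower in 20 of 24 cases (0.0179), the monocyte list in 14 of 15 (0.023) and chromatin enzymes in 18 of 23 (0.0245). Myeloid transcription factors (17 of 21) and antigen presentation (13 of 16) each had 0.0359, and conventional dendritic markers (8 of 12 lower) had 0.0418. Markers of other cells were higher, namely NK cells (11 of 12, 0.0179) and HSPC (12 of 14, 0.0413). Cluster 0 held 70.4 to 93.9% of monocyte-like nuclei in stroke-treated and 28.2 to 86.1% in stroke libraries, and without cluster 0, as with signal concentration as a covariate, 0 lists passed. Without Stroke 3 the count was 0, and without Stroke-treated 1 it was 2.

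Socs3, the feedback inhibitor of cytokine signalling (chromosome 11, 117966079 to 117970336), had 18.8 ± 6.14 CPM in stroke-treated (SD, n = 3) and 39.3 ± 10.2 in stroke monocyte-like nuclei (SD, n = 3). Cmklr1, the chemerin receptor gene, had 84.1 ± 7.60 and 128 ± 16.5 CPM. Junb had 167 ± 40.8 and 275 ± 89.4 CPM, and Fos 59.3 ± 9.20 and 86.4 ± 11.5. The chemokine genes Ccl4 and Ccl3 were at -0.61 (SE 0.23) and -0.53 (SE 0.21), Trem1 at -0.46 (SE 0.17) and Tlr2 at -0.50 (SE 0.20). The integrin gene Itgam was at -0.68 (SE 0.26), Egr1 at -0.62 (SE 0.25), Cebpb at -0.71 (SE 0.29) and the mTOR inhibitor Tsc1 at -0.74 (SE 0.24). Csf2ra, a chain of the GM-CSF receptor, was at -0.43 (SE 0.17), the DNA methyltransferase Dnmt1 at -0.53 (SE 0.23) and H2-K1 at -0.68 (SE 0.31). Il1b had 44.3 ± 4.53 and 40.6 ± 17.6 CPM, a log2 fold change of 0.00 (SE 0.23). Genes nearest to the threshold on the higher side, such as Lce1b at 1.61 (SE 0.47) and Sfrp1 at 1.86 (SE 0.56), had under 5 CPM in every group. Of 18507 genes, 0 passed in edgeR (smallest adjusted p 0.635) and 0 in DESeq2, with 507 (2.74%) at an unadjusted p under 0.05. Of 257105 peaks, 0 passed in both tools, with 6675 (2.60%) at an unadjusted p under 0.05. With the set of libraries as a block, 428 genes passed, 381 of them higher; with the 4 large libraries alone, and so with 1 stroke library, 2062 genes did.

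In HSPC-like nuclei, monocyte genes were lower in stroke-treated libraries, with 13 of 15 members and a median of -0.12 (camera adjusted p = 0.0416; adjusted p = 0.728 with an estimated correlation). Without Stroke 3, Stroke-treated 1 or Stroke-treated 2 the count of passing lists was 0, and without Stroke 2 it was 2. It was 0 too with signal concentration as a covariate, with the replicate block and with gene spans without flanks. Pattern recognition receptors were higher in 12 and lower in 10 cases (0.856), and interferon response genes in 10 and 10 (0.523). P2rx7, the ATP-gated channel that triggers the NLRP3 inflammasome (chromosome 5, 122643927 to 122692336), had 87.1 ± 9.16 CPM in stroke-treated (SD, n = 3) and 133 ± 11.3 in stroke libraries (SD, n = 2). The peptide transporter Tap2 had 62.9 ± 17.3 and 92.6 ± 3.67 CPM. Srebf2 was at -0.30 (SE 0.11), the deacetylase Hdac4 at -0.26 (SE 0.09), the NF-κB inhibitor Tnfaip3 at -0.35 (SE 0.16), Cx3cr1 at -0.37 (SE 0.16) and Hexb at -0.46 (SE 0.14). Cdh18, a cadherin gene, had 126 ± 37.9 and 66.7 ± 27.6 CPM, and Trhde, Grm5, Lrrc4c and Brinp3 were higher too, at 1.46, 0.75, 0.87 and 0.97. Il1b was at -0.42 (SE 0.26), Il1r1 at -0.10 (SE 0.12) and Spi1 at 0.01 (SE 0.13). With the set of libraries as a block, 23 genes passed. In the main fit no gene passed (0 of 17507 in edgeR, smallest adjusted p 0.0803, 0 in DESeq2), and 760 (4.34%) had an unadjusted p under 0.05. The edgeR adjusted p of P2rx7 was 0.106, and its log2 fold change was -0.54 (SE 0.12), or 0.01 relative to T-like nuclei of the same library. Without Stroke 2, which leaves 1 stroke library, 32 genes passed, and without Stroke-treated 2, 23 did.

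**Figure D4:**
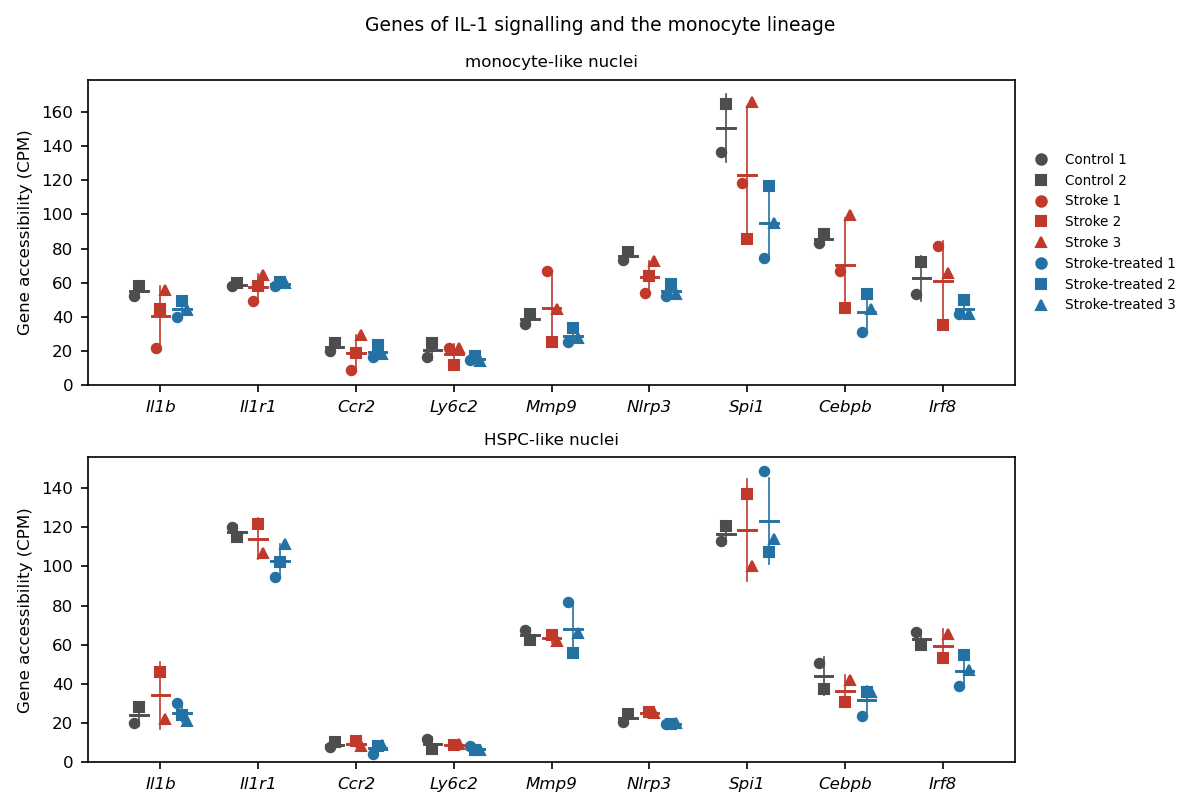
Accessibility in CPM (y axis) of 9 genes of IL-1 signalling and the monocyte lineage (x axis) in monocyte-like and HSPC-like nuclei; points are libraries and bars are group means with the SD. Il1r1 in HSPC-like nuclei lay at 114 ± 10.3 CPM in stroke and 118 ± 3.61 CPM in control libraries.

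The third comparison set stroke-treated against control libraries and is given as a summary. In HSPC-like nuclei, 75 genes rose and 1 fell past the threshold in edgeR (76 of 17507, Benjamini-Hochberg), while DESeq2 gave 10 higher and 0 lower. The genes in the next sentences were chosen after their values were seen. The 1 gene that fell was P2rx7, at -0.56 (SE 0.12, edgeR adjusted p = 0.00725), with 87.1 ± 9.16 CPM in stroke-treated (SD, n = 3) and 134 ± 8.79 in control libraries (SD, n = 2). Among those that rose were Ptprd at 1.16 (SE 0.15, edgeR adjusted p = 7.12e-06), Lrp1b at 1.29 (SE 0.18), Cdh12 at 1.16 (SE 0.17) and Erbb4 at 1.41 (SE 0.23), long genes best known from neurons and epithelia. Signal concentration was 11.3% in control and 7.06 to 9.96% in stroke-treated libraries, so as a covariate it also takes up the group difference, whatever its cause. The same 75 genes were higher in T-like nuclei too, 75 of 75, with a median of 1.35 against 1.01 in HSPC-like nuclei. Relative to T-like nuclei of the same library, in a limma test on differences of log2 CPM, 0 genes passed. Without Control 2 the count was 4, without Stroke-treated 3 it was 27, without Control 1 it was 30, and with signal concentration as a covariate it was 0. Leaving out Stroke 2 or Stroke-treated 2 gave 117 and 130.

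Over all nuclei, 7 lists were lower and 2 higher in stroke-treated than in control libraries, and the same counts came from monocyte-like nuclei. With an estimated correlation 0 lists passed in both, with a smallest adjusted p of 0.588 and 0.532. Signal concentration was 7.06 to 9.96% in stroke-treated and 11.3% in control libraries, and with it as a covariate 3 lists passed over all nuclei and 2 in monocyte-like nuclei. Cluster 0 held 70.4 to 93.9% of monocyte-like nuclei in stroke-treated and 14.6 to 33.1% in control libraries, and without it 0 lists passed. AP-1 genes were lower in 16 of 17 cases in both, with medians of -0.37 (camera adjusted p = 0.00191) and -0.68 (0.000497). Antigen presentation genes were lower in 13 of 16 cases in both, at medians of -0.39 and -0.61 (0.00637 and 0.0121). Without Control 2, 5 lists passed over all nuclei. Erythroid and HSPC markers were higher over all nuclei (0.0424 and 0.0497), and HSPC and NK markers in monocyte-like nuclei (0.0121 each). Cebpb was at -0.57 (SE 0.22) over all nuclei and -0.98 (SE 0.31) in monocyte-like nuclei, Nlrp3 at -0.36 (SE 0.12) and -0.46 (SE 0.18), and Irf8 at -0.39 (SE 0.15) and -0.49 (SE 0.30). Spi1, the master factor of myeloid cells, was at -0.30 and -0.65, Il1b at -0.29 and -0.30, Il1r1 at -0.03 and 0.02, Ccr2 at -0.18 and -0.20, Ly6c2 at -0.33 and -0.41 and Mmp9 at -0.27 and -0.42. In HSPC-like nuclei Il1b was at -0.08, Il1r1 at -0.16, Ccr2 at -0.18, Ly6c2 at -0.48, Mmp9 at -0.04, Nlrp3 at -0.22, Spi1 at -0.03, Cebpb at -0.31 and Irf8 at -0.33.

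No single gene passed in edgeR over all nuclei (0 of 18542, smallest adjusted p 0.128, 6301 at an unadjusted p under 0.05) or in monocyte-like nuclei (0 of 18507, 0.109, 6997). DESeq2 called 1185 higher and 41 lower over all nuclei, and 2205 higher and 158 lower in monocyte-like nuclei. Adjusted over the list alone, 15 list members passed over all nuclei, 42 in monocyte-like and 1 in HSPC-like nuclei. Peaks gave 0 in edgeR and DESeq2, with 66021 of 266857 at an unadjusted p under 0.05 over all nuclei and 46507 of 257105 in monocyte-like nuclei. With the set of libraries as a block, 74551 peaks and 8204 genes passed over all nuclei. Peaks and genes passed under this block in monocyte-like nuclei as well. Without Stroke-treated 2, 5193 genes passed over all nuclei and 4019 in monocyte-like nuclei. Without Stroke 3, 12861 peaks passed in monocyte-like nuclei, and without Stroke 2, 18 did.

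Whether the antibody moved accessibility opposite to stroke was asked across genes, which are not independent replicates. Both comparisons share the stroke libraries, so unchanged groups give a negative correlation, -0.495 on average over 20 simulated draws. The measured correlation of the log2 fold changes was 0.557 over all nuclei and 0.537 in monocyte-like nuclei: genes higher in stroke than in control libraries tended to be higher again in stroke-treated ones. The covariance was 0.0483 over all nuclei (simulated -0.0301) and 0.101 in monocyte-like nuclei (simulated -0.0662). In HSPC-like nuclei the correlation was -0.385 (simulated -0.574), with a covariance of -0.0377 (simulated -0.0443). The simulation holds no difference shared by all genes of a library, and without Stroke 3 the correlation over all nuclei was -0.119. It was 0.274 without Stroke 2 and 0.154 without Stroke-treated 1.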

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

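The tests with signal concentration as a covariate, the set of libraries as a block, the 4 large libraries alone, gene spans without flanks, without cluster 0 and relative to T-like nuclei were chosen after seeing the data. Groups of 2 or 3 libraries, with 304 nuclei in Stroke 1, limit what can be called. Simulated 1.5-fold changes, all above the median accessibility, were recovered in 15% of genes over all nuclei and in 0% of peaks. Where a fit left 1 library in a group, that library was assumed to vary like the others. Promoter accessibility and motif enrichment were not run. RLE factors and the other clustering resolutions left every count of genes, peaks, lists and shares that was rerun on its side, within 1.5 times its value. At resolution 1.2 the HSPC-like fits also lost Stroke-treated 1, which had 48 such nuclei. The cause was not tested for the values below except where a cause is named.

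Most movement lay in stroke-treated against control, given first. DESeq2 called 1226 genes over all nuclei, 2363 in monocyte-like and 10 in HSPC-like nuclei, against 0, 0 and 76. Binarised counts gave 3222 peaks over all nuclei, 7372 peaks in monocyte-like nuclei and 178 genes in HSPC-like nuclei. Fitting only the compared groups gave 5836 peaks over all nuclei, and total counts without a factor gave 8125 peaks in monocyte-like nuclei. The threshold of 0.1, which passes more by construction, gave 800 peaks in monocyte-like nuclei and 115 genes in HSPC-like nuclei. Without the 5% of nuclei with the highest counts there were 2 peaks in monocyte-like nuclei and 44 genes in HSPC-like nuclei, and without cluster 0 there were 104 genes in monocyte-like nuclei. With signal concentration as a covariate, and relative to T-like nuclei, 0 genes passed in HSPC-like nuclei.

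In stroke-treated against stroke, HSPC-like nuclei gave 14 genes with binarised counts, 8 without a filter and 3 at the threshold of 0.1, against 0. The 4 large libraries alone, with 1 control, 1 stroke and 2 stroke-treated libraries, take the spread from the last pair alone and moved nearly every count. They gave 225 peaks and 336 genes over all nuclei, 4217 peaks and 2062 genes in monocyte-like and 77 genes in HSPC-like nuclei. For stroke against control they gave 3 peaks and 1 gene over all nuclei, 3 peaks in monocyte-like and 3 genes in HSPC-like nuclei. For stroke-treated against control they gave 19238 peaks and 1376 genes over all nuclei, 33327 peaks and 5205 genes in monocyte-like and 137 genes in HSPC-like nuclei.

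The replicate numbers did not pair the samples: deviations from the group means correlated from -0.523 to 0.265 across genes for libraries with the same number. The deviations went with the set of libraries instead. Libraries of different groups correlated from 0.05 to 0.635 within samples 1 to 4 or 5 to 8 of the labels, and from -0.587 to -0.028 across these sets. Deviations of the control pair mirror each other by construction. Those of the larger groups cancel out within the group, so the values within and across sets are tied. The highest pairs were also alike in signal concentration. Stroke 3 and Stroke-treated 2 (0.635) had 11.2 and 9.96%, and Stroke 2 and Stroke-treated 1 (0.481) had 8.53 and 7.06%. Whether the set or signal concentration lay behind the correlations was not tested. With the replicate block, stroke-treated against control gave 5232 peaks and 880 genes over all nuclei and 12383 peaks in monocyte-like nuclei. In HSPC-like nuclei the replicate block gave 10 genes for stroke against control, 2 genes and 0 lists for stroke-treated against stroke. For stroke against control 2 lists passed over all nuclei and 2 in monocyte-like nuclei. With the set of libraries as a block, stroke-treated against control gave 74551 peaks and 8204 genes over all nuclei, 40288 peaks and 9558 genes in monocyte-like and 152 genes in HSPC-like nuclei. This block gave 428 genes in monocyte-like and 23 genes in HSPC-like nuclei for stroke-treated against stroke, and 0 lists in monocyte-like nuclei for stroke against control.

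Gene lists moved most with the correlation. With the estimated one, 0 lists passed in each comparison and nuclei set, where the preset one had passed 1, 9 and 9 over all nuclei, 1, 10 and 9 in monocyte-like nuclei and 1 in HSPC-like nuclei. With signal concentration as a covariate, 1 list passed for stroke-treated against stroke and 3 for stroke-treated against control over all nuclei. In monocyte-like nuclei the counts were 0, 0 and 2 over the 3 comparisons. Without cluster 0, which also leaves out Stroke 1 and most nuclei of the stroke-treated libraries, they were 0, 0 and 0. The covariate gave 0 in HSPC-like nuclei for stroke-treated against stroke. Gene spans without flanks gave 0 lists for stroke against control over all nuclei and 0 for stroke-treated against stroke in HSPC-like nuclei.

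Leaving out each library in turn gave ranges of counts. For stroke against control these were 0 to 1464 peaks in monocyte-like nuclei (1464 without Stroke 3), 0 to 25 genes in HSPC-like nuclei, 0 to 8 lists over all nuclei and 0 to 5 lists in monocyte-like nuclei. For stroke-treated against stroke they were 0 to 32 genes in HSPC-like nuclei, 0 to 10 lists over all nuclei, 0 to 10 lists in monocyte-like and 0 to 2 lists in HSPC-like nuclei, and 0 to 1 class share. That class, the unnamed nuclei, passed without Stroke 2 (edgeR adjusted p = 0.0175). For stroke-treated against control they were 0 to 12861 peaks and 0 to 4019 genes in monocyte-like nuclei, 0 to 5193 genes over all nuclei, 4 to 130 genes in HSPC-like nuclei and 5 to 10 lists over all nuclei. The correlation of both comparisons ran from -0.119 without Stroke 3 to 0.699 without Stroke-treated 2. The sign changed, but unchanged groups gave -0.495 for all libraries and were not simulated without Stroke 3, so a negative value alone shows no reversal. Peaks over all nuclei stayed at 0 in each leave-one-out fit. No gene named by the rule had passed. Over 5780 values of these genes under the alternatives, 73 passed and 253 had the opposite sign, 33 of 267 with signal concentration as a covariate and 33 of 175 relative to T-like nuclei.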

Other observations

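The tests of doublets and of cluster 12 below were chosen after the result was seen, as were the genes and peaks named here. P2rx7, an ATP-gated channel of the inflammasome pathway, was lower in stroke-treated than in control libraries in each of the 9 classes measured. Its log2 fold change was -0.79 (SE 0.27) in monocyte-like, -0.80 (SE 0.37) in basophil-like, -0.52 (SE 0.21) in T-like and -0.39 (SE 0.20) in pDC-like nuclei. It was -0.31 in NK-like, -0.24 in cDC-like, -0.14 in neutrophil-like and -0.06 (SE 0.14) in GMP-like nuclei. T-like nuclei had 87.2 ± 3.26 CPM in control, 81.4 ± 13.1 in stroke and 55.4 ± 21 in stroke-treated libraries. In HSPC-like nuclei the fold change against stroke libraries was -0.54 (SE 0.12), and relative to T-like nuclei of the same library it was 0.01.

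No peak passed, and a few were picked here from those with the smallest p-values. Those described below were all lower, but other peaks with small p-values were higher. In stroke-treated against control, a peak nearest to Sqor was at 2.06 (SE 0.43) over all nuclei. It had 0.337 CPM in control and 1.42 in stroke-treated libraries. A peak in Atg10 was at 2.77 (SE 0.66) in monocyte-like nuclei, with 0.241 and 2.35 CPM. A peak 2262 bp from Ccr2 (chromosome 9, 124098770 to 124099656) had 3.90 ± 0.553 CPM in control, 3.03 ± 0.635 in stroke and 1.13 ± 0.601 in stroke-treated libraries, and the last was -1.63 (SE 0.33, edgeR adjusted p = 0.165) from the first. A peak in Nedd9 was at -1.64 (SE 0.33) in the same comparison. In monocyte-like nuclei a peak in Lamp1, a lysosomal gene (chromosome 8, 13161903 to 13162751), had 7.61 ± 0.193, 3.18 ± 1.83 and 1.17 ± 0.885 CPM (-2.52, SE 0.51, edgeR adjusted p = 0.0604). Peaks in Arhgef2 and Mdga1 were at -2.67 and -2.53. In stroke against control over all nuclei, a peak in Brd3, a reader of acetylated histones, was at -1.35 (SE 0.34, edgeR adjusted p = 0.64).

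The 75 genes that rose in HSPC-like nuclei of stroke-treated against control libraries were long, with a median span of 696 kb against 22.6 kb over the tested genes. Their median log2 fold change was 0.87 over nuclei of 8000 to 20000 counts and 1.01 over all HSPC-like nuclei. The limits were set after the nuclei, and not their values, were counted. Depth per nucleus stays open, since this wide band kept most nuclei, such as 389 of 472 in Control 2. The band also held 6 libraries against 7, as Stroke-treated 1, with 37 such nuclei, dropped out. A difference in signal shared by the whole library stays open and is a candidate explanation: the median was 1.35 in T-like, 1.57 in NK-like and 1.75 in monocyte-like nuclei, with 75 of 75 genes higher in each. Gene length stays open too: 73 of the 75 genes spanned over 100 kb, against 13.7% of the tested genes. The longest 5% of the other genes lay 0.13 above the shorter ones. That value leaves out every gene that passed, while 1.01 is a median of genes that passed. Setting them side by side therefore cannot show how large a part length has. The antibody itself stays open and was not tested apart from this difference, although Stroke 1 and Stroke 2, at 8.74 and 8.53%, had a low signal concentration without it.

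T-like nuclei were found although the sort left out T cells. Doublets of a T cell and a monocyte would lie about midway between NK-like and monocyte-like nuclei in summed CPM of monocyte genes, and the highest position over 7 libraries was 0.15, which argues against them as the main source. T cells that passed the sort stay open, and no biological explanation was tested.

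Nuclei of cluster 12, with open Lilra5, Cd300e, Ace, Ear2 and Nr4a1 as in non-classical monocytes, made up 10.1% ± 0.153 of monocyte-like nuclei in control libraries (SD, n = 2) and 4.68% ± 1.02 in the others (SD, n = 6). This share counts cluster 0, whose name is uncertain. Beside cluster 1 alone, cluster 12 was not lower throughout. Control 1 and 2 held 155 and 439 nuclei of cluster 12 beside 887 and 3249 of cluster 1. Stroke 1, 2 and 3 held 2, 82 and 222 beside 22, 162 and 2562. Stroke-treated 1, 2 and 3 held 37, 205 and 224 beside 17, 1209 and 243. For the share of monocyte-like nuclei, the exact permutation p was 0.0357, the smallest that 28 splits allow. Cluster 12 was 1 of 19 clusters and was picked after seeing the data. Signal concentration predicted 0.56 percentage points of the gap of 5.38 in that share (from -0.21 to 0.81 with 1 library left out). This argues against it as the whole cause of that gap, and the gap itself depends on the name of cluster 0. A loss after stroke may be an explanation and was not tested apart from this gap: as a share of all nuclei, stroke against control was at -1.01 (edgeR adjusted p = 0.431) and stroke-treated against control at -0.92 (0.193).

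The 6 stroke and stroke-treated libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes and peaks the real count was 0 in all nuclei and in monocyte-like nuclei, so 10 of 10 splits reached it by construction and nothing was tested. The highest other split gave 4549 genes over all nuclei and 4895 in monocyte-like nuclei, and 0 peaks in both. Both gene counts came from Stroke 1, Stroke 3 and Stroke-treated 2 against the rest, which points to a structure of the samples. These 3 had the highest signal concentration of the 6 (8.74, 11.2 and 9.96%), while the split by set of libraries gave 0 genes in both. For lists, 1 of 10 splits, the real one, gave 9 over all nuclei and 1 of 10 gave 10 in monocyte-like nuclei, where the highest others gave 7 and 7.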
